A study of Drosophila melanogaster with 6 samples.

How the data were processed

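Total RNA from body wall and wing/hinge fragments of wild-type wing imaginal discs was measured on Affymetrix Drosophila arrays, 3 per fragment. Per the labels' description, RNA was purified on a commercial column kit and targets were made by the manufacturer's usual procedure from about 8 ug of total RNA. The values deposited by the authors are intensities on a linear scale, 1 per probe set and array, read as such from the values themselves. They were positive with 1 decimal, and the 2% trimmed mean over all 14010 probe sets was 300.0 to 300.1 on every array, so the deposited intensities were taken as already scaled to a common level. The summary algorithm, scanner and scaling software are not given in the sources used here. Median intensities ran from 89.6 to 117.8 per array. The labels call the samples biological replicates, and nothing further about separate cultures or dissections was used.

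Groups and replicate numbers were taken from the sample titles. Gene names came from a platform annotation table, in which 12443 of 13966 fly probe sets had 1 gene symbol, 327 had several and 1196 had none. Probe sets with several or no symbols were tested but not named, and 4 called probe sets had no single gene name. By gene ID, 12394 of the 1-symbol probe sets matched the RefSeq gene table of assembly Release 6, and no symbol changed. The files name no genome build, so that table served only for names and for which genes neighbour each other.

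The intensities were used as deposited, because their trimmed means lay within 10% of each other. Values under the floor, the 20th percentile of all 6 arrays pooled (20.4), were set to it before log2 was taken. A probe set was tested if it lay above the floor on at least 3 of the 6 arrays, and 44 control probe sets were left out. Of the values of 23 control probe sets for bacterial, mouse and yeast RNA, 64.5% lay at or under the floor, with a 95th percentile of 55.1 and a maximum of 91.8, so levels below about that range are close to background. A gene at the floor on every array of a group has only a bound there and is given as at least N-fold, which applied to 12 of the called probe sets. Other folds of dim genes are also reduced where single values were raised to the floor. Where several values of a group were raised, their spread is removed as well, which can lower the SE.

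Each probe set was tested with limma (version 3.58.1, R 4.3.3; lmFit and eBayes with default settings, two-sided, no block), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Log2 differences are body wall minus wing/hinge. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so none was used for single genes. The 24 gene lists were fixed from textbook knowledge before the data were examined and tested with limma's camera (two-sided, preset inter-gene correlation 0.01, adjusted over the lists). A gene with several probe sets was represented by the one with the highest mean log2 value. Synonyms in the lists were matched to current symbols afterwards. Listed genes without a probe set of their name, or that failed the filter, were not tested. The genes named were the 15 probe sets with the largest positive and the 15 with the largest negative difference among called probe sets naming 1 gene whose groups did not overlap, called members of the lists, and uncalled members of the body wall, wing pouch and hinge lists. Uncalled members of other lists and other genes are named where a count or a candidate source of RNA needed them, and were chosen after their values were seen.

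Body wall 1 and body wall 2 have aliases with the number 2 in the labels, the latter with an added R. The SD of their log2 differences was 0.814, within the 0.735 to 0.868 of the other pairs of arrays of 1 group. By a rule set before the data were examined they were therefore counted as 2 samples. These 2 arrays lie on different sides of the split by brightest values described below, which can raise this SD. It therefore cannot exclude that they are repeats of the same RNA, which the labels do not state. Alternatives covered scaling, the floor, the filter, the variance model, replicate blocks, the averaging of body wall 1 and 2, each array left out, a 2-fold threshold and other list tests. The block by brightest values, the split at 20000 that defines it, a floor from control probe sets and fits on each set of 3 arrays were added after seeing the data. The fit was tested on simulated data with the spread of the 11698 probe sets: of 50 probe sets changed at each size, 6% were recovered at a log2 difference of 1, 58% at 2, 80% at 3 and 92% at 4, with 9 false calls among 127. Differences near 2-fold were therefore mostly missed.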

Results

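Affymetrix expression arrays were hybridised with RNA from fragments of the wing imaginal disc of wild-type Drosophila melanogaster. The wing disc is the larval epithelial sac that forms the adult wing, the wing hinge and the dorsal body wall of the thorax (the notum). Late larval discs had been cut into a body wall fragment and a fragment holding the wing and hinge primordia, and each fragment was measured on 3 arrays, described in the labels as biological replicates. The labels state the purpose as a screen for transcripts with restricted positions in the disc, and the comparison made here is body wall against wing/hinge. The table held 13966 probe sets for fly RNA, of which 12443 named 1 gene. Between 77.1% and 83.1% of them lay above the intensity floor of 20.4 on each array, and the number of arrays limits the precision.

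The test called a small set of genes with large differences, the kind that 3 arrays per fragment could detect. In simulated data 6% of changed probe sets were recovered at a log2 difference of 1 and 58% at 2. Smaller differences were therefore mostly missed, and the calls are not a count of all that differs. Without adjustment, 1049 probe sets had a limma p under 0.05. Chance alone puts many probe sets under that threshold, so such counts, here and below, do not count real differences. Of 11698 probe sets tested, 107 were called (limma, Benjamini-Hochberg adjusted p under 0.05), 69 higher in body wall (62 named genes) and 38 higher in wing/hinge (35 named genes). With values under the floor set to it, the log2 differences of the calls ran from 4.75 (SE 0.27) for the mesodermal factor twi to -6.10 (SE 0.32) for the secreted protein gene peg. In 31 of the calls, pnr, tup, dve and pdm2 among them, the mean of the lower fragment lay under the floor. Their differences are understated, so the order at either end is not settled. Raising values to the floor also removes their spread, which can lower the SE and p. Calls rose from 75 of 13198 tested with the floor halved to 132 of 9897 with it doubled. Every called probe set differed at least 2-fold, and 49 of the body wall calls and 27 of the wing/hinge calls at least 4-fold. In all 107 the 3 values of one fragment lay above the 3 of the other, which held for 1756 of the 11698 tested, where chance gives 10%.

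**Figure D1:**
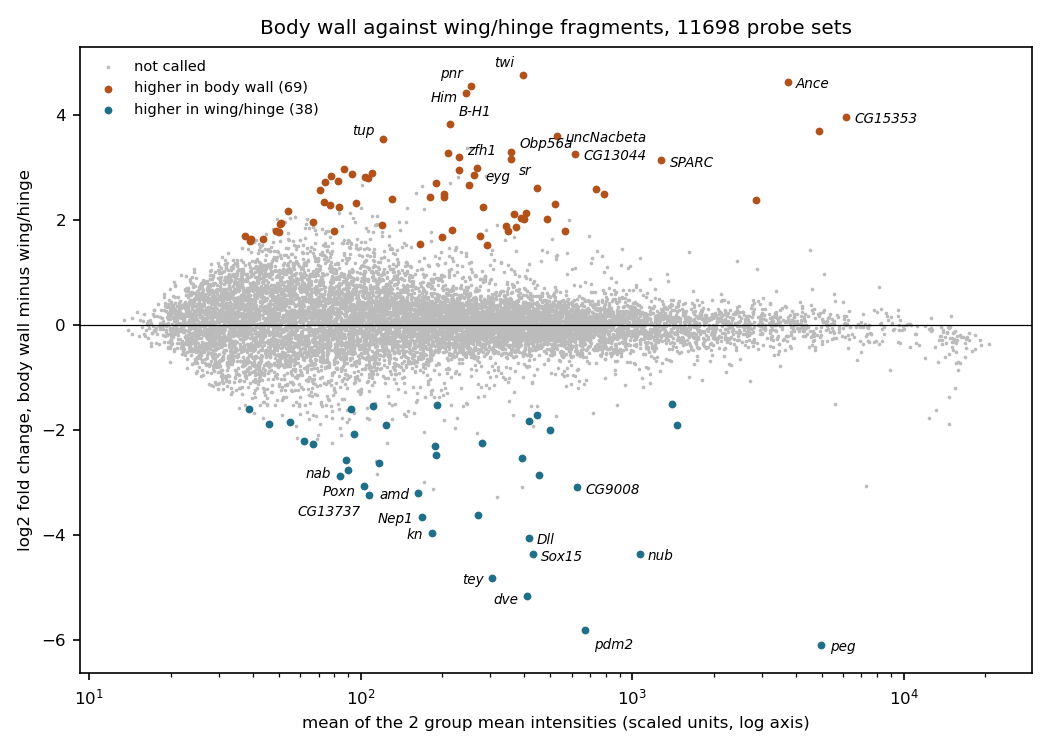
Log2 difference (body wall minus wing/hinge) of each of the 11698 probe sets tested, against the mean of the 2 group mean intensities (scaled units, log axis). Coloured points are the 69 probe sets called higher in body wall and the 38 called higher in wing/hinge, and the named genes lie between 4.75 for twi and -6.10 for peg. Values under the floor were set to it, so differences of genes at background in 1 fragment are understated and their order is not settled.

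Genes of body wall patterning made up part of the body wall calls. The GATA factor gene pnr measured 497 ± 143 in body wall and 15.1 ± 8.39 in wing/hinge (mean intensity ± SD, n = 3 each), a log2 difference of 4.55 (SE 0.28; limma adjusted p = 0.00161). Also higher in body wall were the homeobox gene B-H1 (3.82, SE 0.34; limma adjusted p = 0.00627), the tendon cell factor sr (3.17, SE 0.25; limma adjusted p = 0.0036) and the Pax gene eyg (2.98, SE 0.42; limma adjusted p = 0.032). The call of eyg ended with 5 of the 6 arrays left out in turn, and also with the arrays blocked by their brightest values, a split described in the last paragraph. Of the 16 tested members of the list of body wall patterning genes, these 4 were higher in body wall, 2 were higher in wing/hinge and 10 did not pass the test. Adjusted over the list alone the counts were 7 and 3. The T-box genes Doc2 (-2.30, SE 0.32) and Doc3 (-1.92, SE 0.29) were the members higher in wing/hinge, and their calls ended with any 1 array left out and with that block. Members that did not pass were B-H2 at 2.04, ush at 1.17, tsh at 1.01, caup at 0.69, ara at 0.66, mirr at 0.31, emc at 0.22, Dr at -0.53 and Doc1 at -1.53. A further one, the LIM homeobox gene tup, gave 1.43 (limma adjusted p = 0.557) at its brighter probe set. A dimmer one was at the floor on every wing/hinge array and at least 11.5-fold higher in body wall (limma adjusted p = 0.00154). As a group the list lay toward body wall (mean log2 difference 0.99; limma camera adjusted p = 0.000981), with an adjusted p = 0.116 with an estimated correlation.

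Markers of adult muscle precursors, the mesodermal cells that lie under the notum epithelium, gave 5 of 12 tested members higher in body wall, none higher in wing/hinge and 7 that did not pass the test. Adjusted over the list alone the counts were 6 and 1. The gene twi measured 763 ± 20.8 in body wall and 29.2 ± 9.08 in wing/hinge (SD, n = 3 each; limma adjusted p = 0.00154). Him, an inhibitor of muscle differentiation, differed by 4.41 (SE 0.28; limma adjusted p = 0.00161), the zinc finger homeodomain gene zfh1 by 3.19 (SE 0.45; limma adjusted p = 0.0323), the FGF receptor gene htl by 2.88 and the transmembrane protein gene kon by 1.79. The calls of zfh1 and kon ended with any 1 array left out and with the block. Members that did not pass ran from 1.25 for CadN to -0.77 for Ama and kirre. The list mean was 1.52 (limma camera adjusted p = 4.61e-06), with an adjusted p = 0.112 with an estimated correlation.

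Wing pouch patterning genes gave the opposite picture, with 6 of 15 tested members higher in wing/hinge, none higher in body wall and 9 that did not pass. Adjusted over the list alone, 7 were higher in wing/hinge and 1 in body wall. The POU factor genes pdm2 and nub differed by -5.82 (SE 0.28; limma adjusted p = 0.00115) and -4.37 (SE 0.32; limma adjusted p = 0.00342), with -3.62 at a further nub probe set, whose call ended in 5 of the 6 fits with 1 array left out, and -3.14, not called, at another. For pdm2 the intensities were 16.6 ± 11.5 in body wall and 1329 ± 290.5 in wing/hinge (SD, n = 3 each), while 2 dimmer probe sets of it gave -1.12 and -1.20 and did not pass. The homeobox genes dve and Dll differed by -5.17 (SE 0.24) and -4.07 (SE 0.55), the T-box gene bi by -2.49 (SE 0.30) and the POU gene vvl by -1.84 (SE 0.23). The calls of Dll and bi each ended with 5 of the 6 arrays left out in turn, and that of vvl with any 1. All 3 also ended with the block. The selector gene vg measured 734 and 1597 (log2 difference -1.12, SE 0.26; limma adjusted p = 0.174), and fj, which passed toward body wall over the list alone, gave 1.27 (93.9 against 41.5). The other uncalled members bs, salm, salr, ap, rn, kni and knrl gave 0.87, 0.01, -0.19, -0.25, -0.46, -0.55 and -0.60. At 3 further probe sets rn gave -1.94 (limma adjusted p = 0.0775), -1.64 and -2.17, none called. The list mean was -1.65 and its median -0.60 (limma camera adjusted p = 7.3e-10), with an adjusted p = 0.112 with an estimated correlation.

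Hinge patterning genes went both ways. Of 11 tested, 1 was higher in body wall, 2 were higher in wing/hinge and 8 did not pass, and 3 and 3 passed when adjusted over the list alone. Ance, which encodes a peptidase related to angiotensin converting enzyme, measured 7184 ± 2167 in body wall and 293 ± 90.8 in wing/hinge (SD, n = 3 each; log2 difference 4.63; limma adjusted p = 0.0036). The zinc finger homeodomain gene zfh2 (-2.87, SE 0.23, and -1.52, not called, at a further probe set) and the Pax gene Poxn (-3.07, SE 0.28) were higher in wing/hinge. The odd-skipped family genes drm, odd and sob gave 1.61, 1.20 and 1.09 without passing the test, and Wnt6, ct, Dr, ds and upd1 gave 0.02, -0.20, -0.53, -0.54 and -1.53. The list as a whole did not pass the test (mean -0.02; limma camera adjusted p = 0.494, and adjusted p = 0.689 with an estimated correlation).

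**Figure D2:**
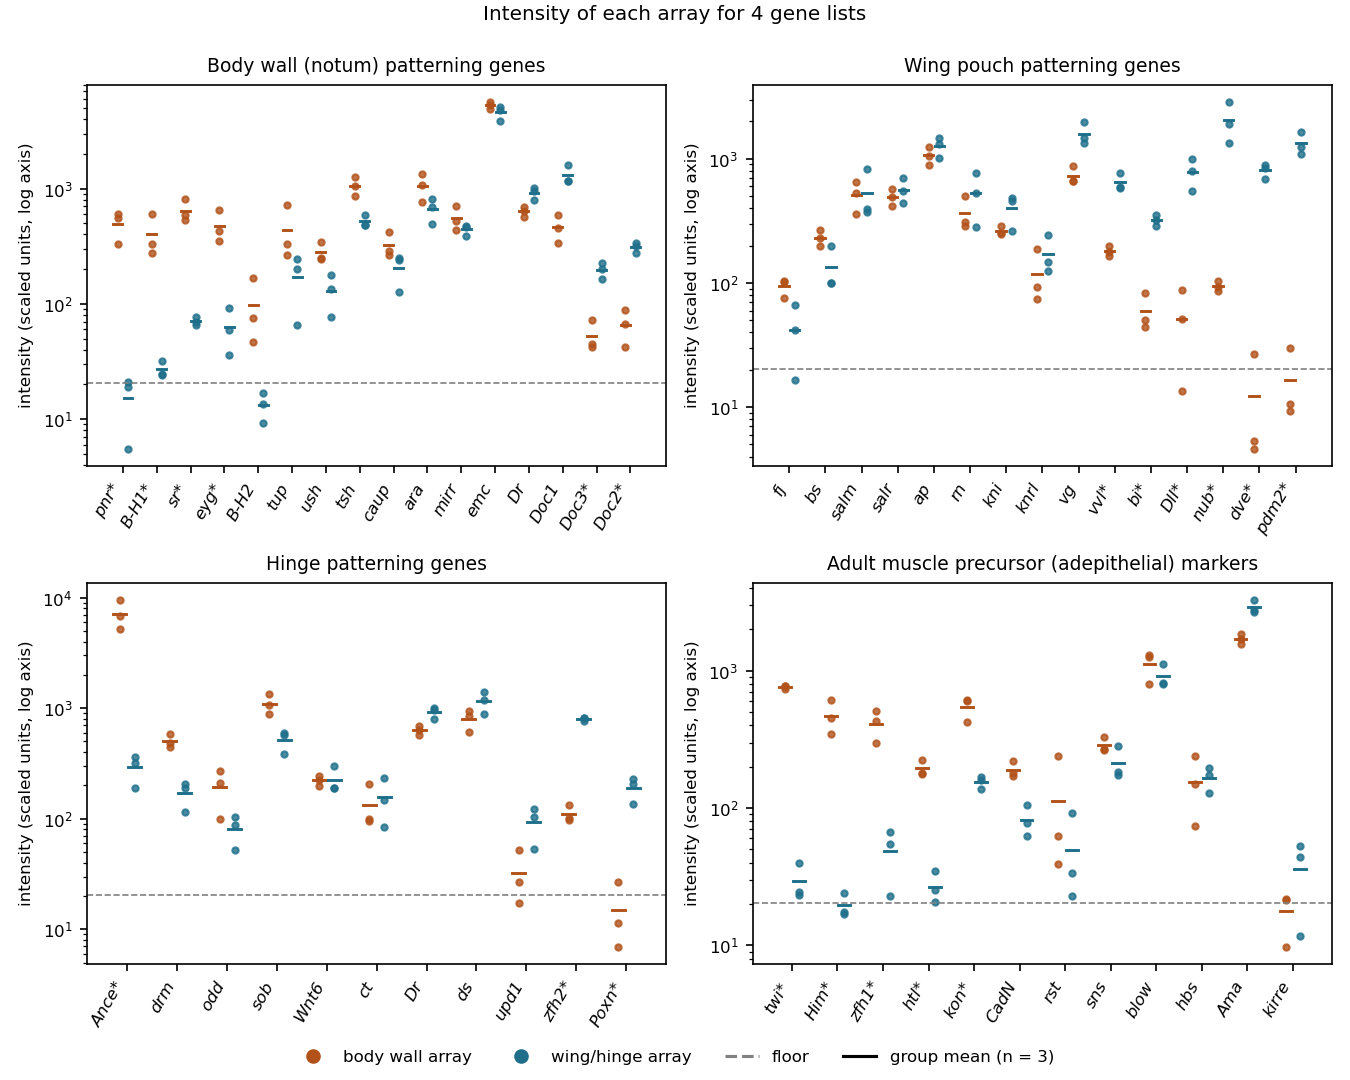
Intensity (scaled units, log axis) on each array for the tested members of 4 gene lists, 1 probe set per gene, with a bar at each group mean (n = 3) and a dashed line at the floor of 20.4. An asterisk marks a called gene: pnr, B-H1, sr and eyg lie higher in body wall, and pdm2, dve, nub, Dll, bi and vvl higher in wing/hinge.

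Other genes with large differences fell outside these lists. In body wall, CG15353 measured 11612 against 715 (log2 difference 3.97, and 3.70 at a further probe set). The log2 differences of uncNacbeta, the odorant-binding protein gene Obp56a and CG13044 were 3.60, 3.28 and 3.26. In wing/hinge, peg measured 9822 ± 1755 against 147 ± 44.7 in body wall (SD, n = 3 each; limma adjusted p = 0.00138), and tey was at least 28.2-fold higher than in body wall, where it was at the floor on every array. The HMG-box gene Sox15 differed by -4.38 and -2.54 at 2 called probe sets, CG13737 by at least 9.54-fold and CG9008 by -3.10. For Nep1, a neprilysin peptidase gene, and amd the called probe sets gave -3.66 and -3.20, while brighter probe sets of the same genes gave -0.36 and 0.29 and did not pass. For nab the called probe set was at least 7.34-fold higher in wing/hinge and a brighter one gave -3.10 (limma adjusted p = 0.073). Of the 22 genes with several tested probe sets and at least 1 called, 3 had a probe set pointing the other way, namely amd, rec and zormin. The last 2 names were chosen after their values were seen. With single arrays left out, the calls of CG13044 and of both Sox15 probe sets each ended in 5 of 6 fits, those of Obp56a and nab in 3, that of uncNacbeta without body wall 2, and that of amd in all 6. The calls of CG13044, Sox15 and amd also ended with the block.

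Among signalling pathways, the hh list lay toward wing/hinge (11 tested; mean -0.75; limma camera adjusted p = 0.00075, and adjusted p = 0.116 with an estimated correlation). Its only called member was the COE factor gene kn (-3.97, SE 0.24; limma adjusted p = 0.00154), and 3 passed when adjusted over the list alone. The uncalled members inv, en and hh gave -1.12, -1.05 and -1.01. The Notch list lay toward body wall (12 tested; mean 0.51; limma camera adjusted p = 0.041, and adjusted p = 0.228 with an estimated correlation), with E(spl)m6-BFM (2.75, SE 0.35) as its only member called, over the list alone as well. The call of E(spl)m6-BFM ended with 5 of the 6 arrays left out in turn, and that of the list held in 12 of 24 alternatives. No member of the wg (5 tested of 15 listed), dpp (11 of 13), Egfr (7 of 11) or Jak/Stat (6 of 10) lists was called. Most of the wg list was thus not tested. Adjusted over each list alone, 1 dpp gene passed toward body wall and 1 Jak/Stat gene in each direction, and camera called none of these lists with the preset or an estimated correlation. Of 6 Hox and appendage identity genes, Dll alone was called, with 2 toward body wall and 1 toward wing/hinge over the list alone.

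Of 21 matrix and adhesion genes tested, SPARC, which encodes a collagen-binding protein (2295 ± 77.0 against 265 ± 47.3, SD, n = 3 each; log2 difference 3.13, limma adjusted p = 0.00345), the perlecan gene trol (2.44, SE 0.32) and the type IV collagen gene Col4a1 (2.31, SE 0.26) were higher in body wall. The integrin gene if was higher in wing/hinge (-1.52, SE 0.23), and 17 did not pass, among them the other type IV collagen gene vkg at 2.82 (limma adjusted p = 0.171). The calls of trol and Col4a1 ended with 5 and 4 of the 6 arrays left out in turn, and that of if with any 1. Those of trol and if also ended with the block. Adjusted over the list alone the counts were 5 and 2. The list mean was 0.57 (limma camera adjusted p = 0.0349, and adjusted p = 0.452 with an estimated correlation), and this call held in 14 of 24 alternatives. The haemocyte list, which shares Col4a1, vkg and Pxn with it, also lay toward body wall (10 tested; mean 1.09; limma camera adjusted p = 0.000149, and adjusted p = 0.219 with an estimated correlation). Col4a1 was its only called member, and it, vkg and ush passed over the list alone. Of the other haemocyte markers, Hml measured 73.1 in body wall and 37.2 in wing/hinge and Pxn 151 and 94.5, without passing the test.

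Lists of other cell types and general processes gave 1 call in all, egr, a TNF ligand gene among 6 cell death genes tested, higher in body wall by 2.34 (SE 0.26; limma adjusted p = 0.015). It also passed over the list alone, and its call ended with 5 of the 6 arrays left out in turn. No member was called of the lists for fat body (8 tested), tracheal cells (12), larval muscle (7), neurons and glia (11) or peripodial membrane and other discs (5). The same held for proneural genes (14), cell cycle genes (15 of 24 listed), ecdysone response genes (19), cytosolic ribosomal proteins (35) and heat shock and immune genes (5 of 20 listed). Over each list alone, 3 tracheal genes passed toward body wall and 1 toward wing/hinge, 1 ecdysone and 1 peripodial list gene passed toward body wall, and none passed in the others. Camera called none of these 11 lists with the preset or an estimated correlation, while over 24 alternatives it called ribosomal proteins in 4, the peripodial list in 3 and fat body in 1. For 6 of the 24 lists the mean, the median and the test differed in sign (dpp, Egfr, Hox, heat shock and immune, cell death, tracheal), and none of these was called.

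**Figure D3:**
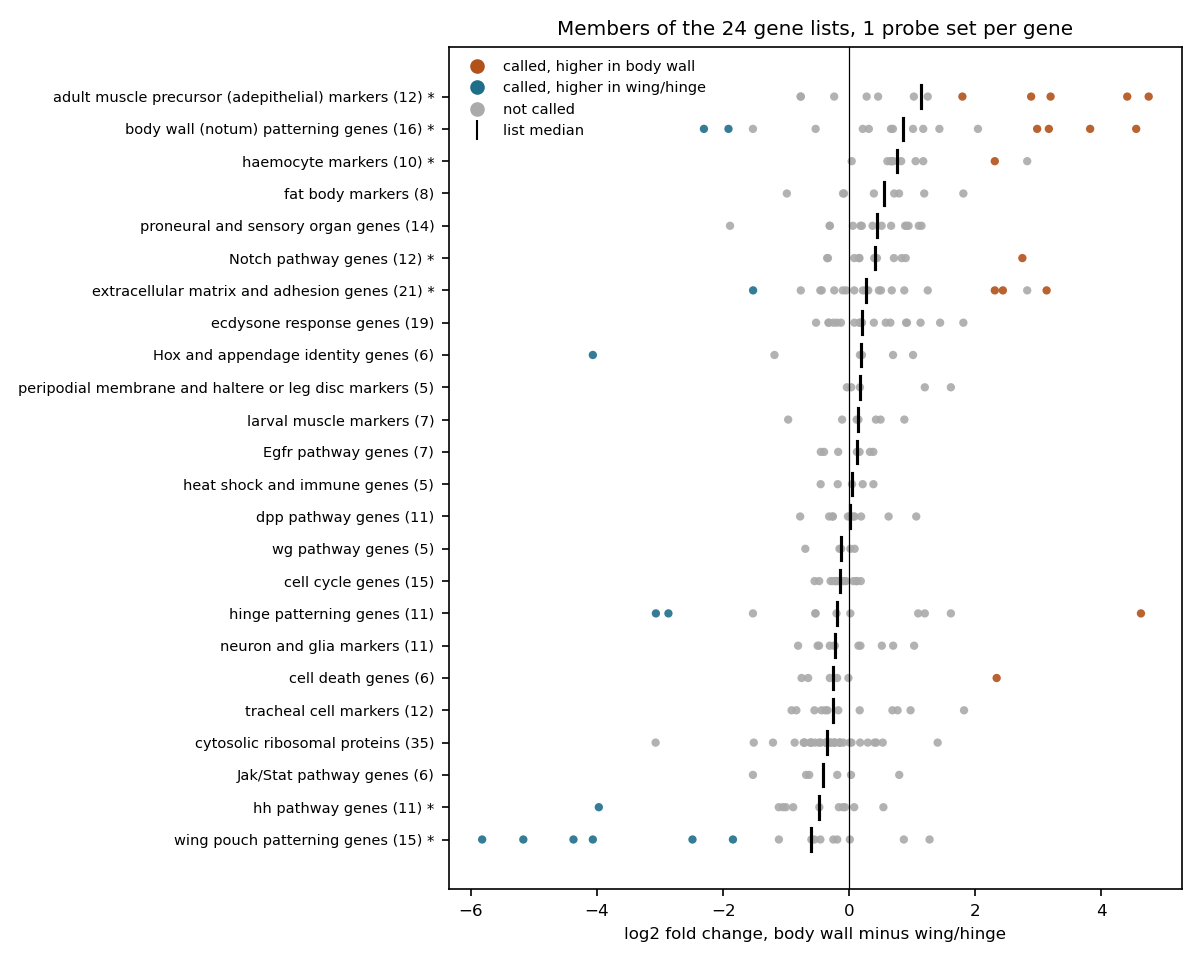
Log2 difference (body wall minus wing/hinge) of each tested member of the 24 gene lists, 1 probe set per gene, ordered by list median (black bar), with the number tested in parentheses. Coloured points are called genes, and an asterisk marks the 7 lists with a camera adjusted p under 0.05 at the preset correlation, none of which passed with an estimated correlation.

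The arrays also split by their brightest values, a division seen only in the data. Body wall 1, wing/hinge 1 and wing/hinge 2 reached 24976 or more, while body wall 2, body wall 3 and wing/hinge 3 stayed at or under 14881. The 3' to 5' intensity ratio of the actin control was 1.92 to 2.98 on the former and 1.12 to 1.28 on the latter. With this split as a block limma called 52 probe sets, 34 higher in body wall and 18 higher in wing/hinge, of which 51 were among the 107. Of the 42 probe sets named by size or as called list members, 13 lost their call (adjusted p 0.0528 to 0.103), for CG13044, zfh1, eyg, trol, kon, if, vvl, Doc2, Doc3, bi, amd, Dll and the larger Sox15 difference, which kept 91.1% to 108% of their size. Each set of 3 arrays holds 1 fragment on a single array (wing/hinge 3 in the narrow set, body wall 1 in the wide set), which is assumed to vary like the others. Within each set limma called none, with 752 probe sets at an unadjusted p under 0.05 on the narrow-range arrays and 983 on the wide-range arrays. There twi differed by 5.01 and 4.64, pnr by 4.82 and 4.02, pdm2 by -5.48 and -6.13 and peg by -5.54 and -6.81. Non-overlapping groups force these directions, so they are no test of the calls. For the lists, only means are given within each set, as a single array cannot carry a test. With the block the limma camera adjusted p of body wall patterning genes was 0.00203 (0.116 with an estimated correlation over all 6 arrays). Their list mean was 0.90 on the narrow-range and 1.01 on the wide-range arrays. For wing pouch genes the camera adjusted p with the block was 8.96e-09 and the means were -1.61 and -1.55. For muscle precursor markers they were 8.63e-05, 1.52 and 1.38 (adjusted p = 0.112 for each of these 2 lists with an estimated correlation). For the hh list they were 0.000266, -0.85 and -0.77 (adjusted p = 0.116 with an estimated correlation). For haemocyte markers they were 6.55e-07, 1.24 and 1.36 (adjusted p = 0.219 with an estimated correlation). For Notch genes they were 0.0556, 0.47 and 0.42, and for matrix and adhesion genes 0.0604, 0.63 and 0.46. The estimated correlation was run on the fit without the block only. Leaving out any 1 of the 6 arrays left between 34 and 47 calls, a similar fall whichever array it was. Fewer degrees of freedom alone, those of the fit with the block, took the 107 to 46, so the fall is not ascribed to single arrays. Of the 107 probe sets, 28 were called in all 6 of the fits with 1 array left out and 41 in none. Body wall 1 and body wall 2 carry related aliases in the labels, and a repeat of the same RNA is not excluded. Averaging them as 1 sample left 49 calls, while a variance trend with a robust fit gave 161.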

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

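The tests of the split by brightest values and of its causes were chosen only after the result was seen. On body wall 2, 2 control probe sets for 18S ribosomal RNA, which no comparison used, measured 156.4 (3' end) and 259.8 (middle), above the highest bacterial, mouse or yeast control on that array (59.4). On the other 5 arrays no 18S probe set exceeded the highest such control. No explanation was tested for this signal.

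Of the 10 ways to split the 6 arrays into 3 and 3, only 1 gave the 107 calls, the real one, and the highest of the others gave 1 call, for the split that follows the brightest values. With 10 splits no share under 0.05 can be reached. With the brightest-value split as a block, the median size of the called log2 differences was 2.45 against 2.49, or 98.6% of it (90.8% to 109.7% per probe set). Non-overlapping groups bound that share from below, so a large fall could not have shown. No conclusion on that split as a source of the differences is drawn from it. Calls fell to 52, and the 56 that ended had a median size of 1.97 with the block against 2.00 and a median SE of 0.29 against 0.28. The block leaves 5.65 total degrees of freedom in place of 6.80. With 6.80 the t values from the block gave 121 calls, 100 of them among the 107, and with 5.65 those from the fit without it gave 46, so the fewer degrees of freedom lowered the count. A test planned earlier, the direction within each set of arrays, was met by 107 of 107 but is void, since non-overlapping groups force it. The kept size was tested in its place, but non-overlapping groups limit it as well, so it is void too. The small spread that a call needs also favours a high kept size.

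SPARC and Col4a1 were higher in body wall, and RNA from haemocytes or fat body carried along with that fragment may contribute. The other 8 haemocyte markers tested had a median log2 difference of 0.687, none called and all 8 above 0, and 5 of the list's named genes also stand on other lists. The brightest were PPO2 at 342 against 167, ush at 280 against 130 and Pxn at 151 against 94.5. A dimmer PPO2 probe set measured 23.2 to 38.5 in body wall and 19.7 to 55.6 in wing/hinge. The largest difference of the 8 was that of ush (1.17, passing over the list alone), which is also on the body wall patterning list. Mean intensities of Hml, eater and srp lay under the highest bacterial, mouse or yeast control value of 91.8 in both fragments. The 8 fat body markers had a median of 0.552, none called, 5 above 0 and 3 below. Lsp2 measured 446 against 212 and Fbp1 421 against 157, while Yp2 went the other way at 113 against 176. Each median lay between the bounds of 0.5 and 1 set before the result was seen, so neither source can be told apart from expression in body wall cells, which was not tested.

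The wide and narrow bright range of the arrays did not follow the fragments, and no biological explanation was tested. In the top 1% of probe sets the wide-range arrays lay 1.02 higher on the log2 scale, against 0.47 from 3000 up and 0.04 from 1000 to 3000. An earlier test took this as support for compressed bright values on the other 3 arrays, but it is void, since the split was set by the maximum of each array. The order of the 140 probe sets in the top 1% was tested in its place. Between arrays of 1 fragment, rank correlations were 0.615 and 0.924 within a set and 0.0341 to 0.412 between the sets, a gap of -0.203 from the lower of the former to the highest of the latter. With 2 pairs of arrays within a set, this argues against compression that keeps the order of bright values as the whole cause. Compression of single probes, which can change that order, was not tested and stays open. RNA or target quality as the whole cause is argued against by the cre controls, which are added after the target is made, since the lowest wide-range value was at least 1.20 times the highest narrow-range value for both ends. Of the 9 probe sets of controls added at that step, the 3 with means from 3000 up (cre and 1 for bioD) and 1 for bioC separated the arrays, while the other 5, with means up to 1020, overlapped (lowest wide-range over highest narrow-range value 0.614 to 0.996). The fly probe sets also differed little there (-0.07 from 300 to 1000). A first test of quality had gone with it: the 3' to 5' ratios of 3 of 3 fly control genes were higher on the wide-range arrays (actin 1.92 to 2.98 against 1.12 to 1.28). The same ratio of cre, which RNA quality cannot move, separated the arrays as well (1.60 to 1.87 against 0.71 to 1.01), so a part played by RNA quality in these ratios stays open.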

How the results depend on the processing

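The alternatives based on brightest values and on control probe sets were added after seeing the data. Every called probe set that an alternative tested kept its direction there. The non-overlapping groups of all 107 force this in every alternative except those that rescale the arrays, so it lends no support. Scaling, floor, pseudocount, no filter and a 2-fold threshold moved the count of 107 by less than 1.5 times. With the floor halved 75 were called and with no filter 85, and each kept 67 of the 107. Of the 30 probe sets named by size, 6 lost their call with the floor halved and 7 with no filter. Counts of calls (total, body wall, wing/hinge) were 161, 98 and 63 with a variance trend and robust fit (85 shared with the 107), 49, 29 and 20 with body wall 1 and 2 averaged, and 52, 34 and 18 with the brightest-value block. With only probe sets above the floor on all 6 arrays they were 78, 56 and 22, where 66 of the 107 were tested. Leaving out 1 array gave 34 to 47, 18 to 34 and 13 to 18, and each set of 3 arrays alone gave 0, 0 and 0 (limma; 752 and 983 at an unadjusted p under 0.05); these fits have fewer samples, and a lone sample is assumed to vary like the others. The replicate block by title number gave 10, 5 and 5, and by alias number 0, 0 and 0 (limma; 1008 at an unadjusted p under 0.05). Deviations of arrays with the same title number correlated at 0.06, -0.16 and 0.19. By alias number, body wall 1 and body wall 2 both go with wing/hinge 2, at 0.18 and -0.16. Body wall 3 goes with wing/hinge 3 at 0.19. The pairs at 0.18 and 0.19 each also lie on 1 side of the split by brightest values. The numbers were not taken to pair the samples, but a pairing by alias number is not excluded. The limma camera adjusted p of body wall patterning genes was 0.0504 with probe sets above the floor on all 6 arrays and 0.116 with an estimated correlation (range over 24 alternatives 7.26e-05 to 0.116). With an estimated correlation it was 0.112 for wing pouch genes and for muscle precursor markers, and all 7 list calls ended. Ribosomal proteins, uncalled, reversed toward body wall on the wide-range arrays alone (adjusted p 0.0393; range 7.09e-06 to 0.904), and were called toward wing/hinge without body wall 1, without wing/hinge 3 and with body wall 1 and 2 averaged. The peripodial and other disc list was called toward body wall on the narrow-range arrays alone (0.0192), without body wall 1 (0.00856) and with the floor from control probe sets (0.046; highest over all alternatives 0.723), and fat body without wing/hinge 2 (0.0394; highest 0.640). Beyond this split for ribosomal proteins, and fewer samples, probe sets or (with the brightest-value block) degrees of freedom, the cause was not tested. Signal over background limits dim genes, as control probe sets reached 91.8.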

Other observations

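Of the tests in this part, that on neighbouring genes was set before its result was seen, and the genes in the next sentences were chosen after their values were seen. The FGF ligand gene ths was higher in body wall (log2 difference 2.85; limma adjusted p = 0.00627), as was its receptor gene htl. The immunoglobulin family genes beat-IIb and beat-IIIc each had 1 probe set higher in body wall (2.87 and 2.33) and a further one that did not pass (1.30 and 0.56). Obp99a (2.49), Idgf4 (2.37), the thrombospondin gene Tsp (1.88 and 1.79 at 2 probe sets) and the aquaporin gene Drip (1.85) were also higher there. In wing/hinge, the zinc finger gene opa (-2.59) and the lipophorin receptor gene LpR1 (-2.63) were higher. At 2 further probe sets LpR1 gave -0.75 and -0.08 and did not pass. Pdfr was at the floor on every body wall array and at least 3.05-fold higher in wing/hinge. Its wing/hinge mean of 62.6 lay under the highest bacterial, mouse or yeast control value of 91.8, so it is close to background. With the brightest-value block the calls of beat-IIIc, Obp99a, Tsp, Drip, opa and Pdfr ended, and those of Tsp, Drip and Pdfr also ended with any 1 array left out. Those of beat-IIIc, opa and LpR1 ended in 5 of these 6 fits, that of Obp99a in 4 and that of beat-IIb in 3. Of 125 families of genes sharing a symbol stem, limma's camera called none, the lowest adjusted p being 0.0953 for the E(spl)m and Obp families, with an adjusted p = 0.947 with an estimated correlation.

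A hypothesis was that neighbouring genes differ together between the fragments. Among 9160 genes placed in order on the chromosomes, 88 of them called, 3 adjacent pairs were called in the same direction, nub with pdm2, CG14567 with CG14566, and htl with sr. In 10000 random reassignments of the calls the 95th percentile was 2 (permutation p = 0.0102, one-sided), and 1 pair fewer would give p = 0.0757. This is consistent with a weak tendency that rests on 3 pairs, but the calls of CG14567 and CG14566 ended with that block and with any 1 array left out, and 1 adjacent pair went in opposite directions. Cross-hybridisation between related neighbours such as the POU genes nub and pdm2 may add to it and was not tested.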
